A study of Mus musculus with 6 samples.

How the data were processed

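Total RNA was extracted from uteri with Trizol and sequenced as 1 library per animal, with 3 control and 3 conditional knockout (cKO) animals processed together, per the labels. Per the submitters' processing notes, reads were handled with HISAT2, SAMtools and featureCounts, without versions, and the build is given as GRCm39. The counting settings for strand and for reads with several matches are not given in the sources used here. Of 25988 genes whose identifiers were found in GENCODE vM21, which is on GRCm38, 25239 had identical coordinates in the deposited table, so its coordinates are read as GRCm38, and that annotation was used for exons and transcripts.

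The deposited signal values are gene counts that the authors divided by 1 size factor per library. This was read from the values: in each column, 100% of values were whole multiples of the column's step within a tolerance of 0.01 reads. Dividing by the step gave whole reads, from 14584450 to 16579573 per library. The size factors equal median-of-ratios factors computed from the same reads. The deposited table also holds the authors' group means, their log2 fold changes and their p-values and adjusted p-values, without a p-value for 318 genes. The tool behind that comparison is not given in the sources used here. In it, 227 genes were higher and 609 lower at an adjusted p under 0.05, and all 190 genes called in the main test are among them with the same direction. In 24 rows a spreadsheet had turned the gene symbol into a date, and all 24 were restored by gene identifier. Where 1 symbol stood on several rows, the row with the highest mean stood for the gene in lists.

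The design fixed before the data were examined foresaw edgeR's quasi-likelihood test for counts and limma for any other unit. Since the deposited values are normalised, the main test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend and robust empirical Bayes. The added 1 shrinks the fold change of genes with few reads. Averaging log2 values can instead enlarge it against the ratio of means, where libraries of a group differ widely. Genes with few reads were removed with edgeR 4.0.16 (filterByExpr by group) on the recovered reads. The 3 control libraries were compared with the 3 cKO libraries, without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The edgeR test foreseen for counts was run on the recovered reads as an alternative, a choice made after seeing the file. It called 31 higher and 120 lower genes, of which 31 and 117 were also called by limma. Of the 38 genes named below with a call by limma, 12 lost it with edgeR. Means are given with the standard deviation over 3 animals, and log2 fold changes with the standard error of the limma fit. Where a library has 0 reads, 3 reads were taken as the upper limit. Such limits cover counting error only, because reads made by PCR without molecular identifiers are not independent molecules.

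The lists of genes, 49 in all, were fixed before the data were examined, and 47 of them had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. The genes named follow a rule fixed at the same time. It takes Tcf21, the 12 largest increases and the 12 largest decreases among called protein-coding genes with a mean of at least 1 CPM, 3 cKO libraries on one side of the 3 controls and a named symbol, and up to 4 members with the smallest p of each list described, plus any steroid hormone receptor. Some genes that the rule takes are not reported here. Acta1 falls outside it and was chosen after its values were seen. Lists of liver, autonomic and enteric neuron, intestinal epithelium, glycolysis and uterine mesenchyme genes were also added then. Exons of other genes that overlap a named gene, and transcripts of other genes with at least 95% identity over at least 100 bases (blastn 2.17.0), were looked up for each named gene and for all members of the smooth and skeletal muscle lists.

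The tests were tried on simulated reads with 200 changed genes, drawn for the comparison of 3 cKO with 3 control libraries with the totals and spread of the real ones. Each gene was drawn independently, and changed genes were taken among those with a mean of at least 1 CPM. Shifts shared by the genes of a tissue were not simulated, so the rates may not carry over to the real libraries. Of 15948 genes fitted, limma called 0% of genes changed 1.5-fold, 20% of those changed 2-fold, 70% of those changed 4-fold and 95.9% of those changed 8-fold, and 7 of 15749 unchanged genes. The alternatives were other scalings, filters, pseudocounts (0.5 and 5), tests (DESeq2 1.42.0, limma-voom and edgeR), a replicate block, other thresholds and leaving out each library in turn. The 6 libraries differ from each other by far more than sampling noise, so none was counted as a repeat of another.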

Results

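Gene expression was measured by bulk RNA sequencing of uterine tissue from 6-week-old, body-weight-matched female mice. The control group held 3 animals with floxed copies of Tcf21, and the conditional knockout (cKO) group held 3 animals with deleted copies. Tcf21 encodes a basic helix-loop-helix transcription factor of mesenchymal cells. Each library came from 1 animal, and the comparison asked which genes TCF21 may act on in the developing uterus. The control libraries held 14585539, 16245685 and 15694613 reads on genes, and the cKO libraries held 16579573, 16008078 and 14584450. Of 26018 genes listed, 16314 passed the filter on low reads. The first principal component of log2 expression carried 35.6% of the variance and placed the 3 cKO libraries apart from the 3 controls. Pearson's r across genes was 0.945 to 0.96 between cKO libraries and 0.88 to 0.919 between controls. Between a control and a cKO library it was 0.884 to 0.93, which overlaps the range between controls, and control replicate 2 had a higher r with cKO replicates 1 and 3 (0.93 and 0.928) than with either other control. Genes are not independent replicates for such a coefficient.

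Tcf21 (ENSMUSG00000045680) lies on chromosome 10 at 22817281 to 22820174 on the minus strand (GRCm38) and has 2 exons. Its normalised read counts were 341.4, 151.9 and 144.1 in control replicates 1 to 3. In the cKO animals they were 26.0 in replicate 1 and 0 in replicates 2 and 3, where a count of 0 allows values of up to 2.93 and 3.31. The control mean was 24.5 times the cKO mean, and all 3 cKO libraries lay below all 3 controls. The fitted log2 fold change was -6.03 ± 1.25 (SE, n = 3 per group), with a 95% confidence interval from -8.94 to -3.13 and a limma Benjamini-Hochberg adjusted p of 0.0765, which missed the threshold of 0.05. Without cKO replicate 1, which held 28 reads of Tcf21, the log2 fold change was -7.62 with a limma adjusted p of 0.00583. The authors' deposited table lists a log2 fold change of -4.61 and an adjusted p of 0.284 for Tcf21. The limma fit averages log2 values, so its fold change can exceed the ratio of the means where some libraries hold no read. The labels do not say which part of the gene was deleted, and reads from any remaining part would be counted in these values.

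Across the transcriptome, 145 genes were lower and 45 genes were higher in the cKO uteri (limma, Benjamini-Hochberg adjusted p under 0.05). Genes of the smooth muscle contractile apparatus were among the largest decreases. Actg2, the smooth muscle gamma-actin, had a normalised read count of 18631 ± 5329 (SD, n = 3) in controls and 198.9 ± 179 in cKO animals, a log2 fold change of -6.86 ± 0.60 (SE). Cnn1, which encodes the actin-binding protein calponin, had a log2 fold change of -5.86 ± 0.55. Nptx2, a secreted neuronal pentraxin, fell from 329.6 ± 90.4 to 10.4 ± 7.67, and Kcnf1, a potassium channel subunit, from 408 ± 331 to 7.07 ± 3.07. Colec10, a secreted collectin, had a mean of 218.6 in controls and no read in any cKO library, which makes it at least 72.6-fold lower when each cKO library is set at its floor of 3 reads. Snap25, a component of the synaptic vesicle fusion machinery, also had no read in the cKO animals and was at least 89.8-fold lower, with control values of 19.5, 98.0 and 693.0. Without control replicate 3, that bound for Snap25 was 19.5-fold. That library held 0.0657% of its reads on genes of autonomic and enteric neurons, a list chosen after seeing the data, against 0.000329% and 0.00702% in control replicates 1 and 2 and at most 0.000288% in a cKO library. Optc, Npy4r, Tmem59l, Syt1, Tmem200c and Klhl32 completed the 12 largest decreases, with log2 fold changes from -6.19 for Optc to -5.06 for Klhl32. Leaving out 1 library moved several of these values by over 1.5 times. Without control replicate 3 the log2 fold changes of Snap25, Npy4r, Tmem59l and Syt1 were -5.49, -5.36, -4.89 and -4.84, and none of the 4 passed. Without control replicate 1 those of Colec10, Snap25 and Npy4r were -8.18, -8.03 and -7.05, and without control replicate 2 those of Tmem59l, Kcnf1 and Tmem200c were -6.40, -4.83 and -4.46, with Kcnf1 still called. Without cKO replicate 1 Actg2, Optc, Tmem59l, Syt1 and Klhl32 were at -7.55, -7.29, -6.73, -6.44 and -5.97, and all but Syt1 passed. Tmem200c was at -5.84 and -4.20 without cKO replicates 2 and 3, and Optc and Syt1 were at -5.48 and -4.82 without cKO replicate 3, in each case without a call. The transcripts of Klhl32 share stretches of at least 95% identity with those of 234 other genes. These matches were up to 132 bases long, and Klhl32 has 7826 exon bases, so its reads in such stretches are uncertain.

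The 12 largest increases by the rule for named genes were smaller than its 12 largest decreases. Pnpla3, a lipid droplet protein, led these increases with a log2 fold change of 2.34 ± 0.40 (SE), from 51.1 ± 28.2 (SD, n = 3) to 244 ± 51.8. Transcripts of 5 other genes share stretches of at least 95% identity with those of Pnpla3, up to 120 bases long. Ppp1r27 rose from 1749 ± 352 to 5946 ± 838, and Ppp1r3c, a subunit that directs protein phosphatase to glycogen, from 933 ± 234 to 2968 ± 462. The circadian transcription factor gene Arntl had a log2 fold change of 1.47 ± 0.21. Myod1, which encodes a determinant of skeletal muscle identity, rose from 95.7 ± 17.5 to 254 ± 10.3. Sh2b2, Dupd1, Relt, Rrad, Card9 and Cxcr4 were also among the 12 largest increases, with log2 fold changes between 1.23 for Cxcr4 and 1.45 for Sh2b2. Genes of the skeletal muscle list took 8.33 ± 1.51% of all reads in cKO libraries and 4.61 ± 1.51% in controls.

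All 190 called genes had their 3 cKO libraries on one side of the 3 controls, a separation that 19.6% of tested genes showed and that chance gives to 10%. Without control replicate 1 there were 117 higher and 347 lower genes, without control replicate 2 there were 82 and 90, and without control replicate 3 there were 58 and 235. Without cKO replicates 1, 2 or 3 in turn, the higher genes numbered 2, 3 and 1 and the lower genes 69, 47 and 42. Leaving out both control replicates 1 and 3, which held transcripts of other tissues, was an alternative chosen after seeing the data. It leaves only control replicate 2. That library also held such transcripts, with 0.00941% of reads on intestinal epithelium genes and 0.00702% on autonomic and enteric neuron genes. Of the 38 called genes named here, 2, 19 and 10 lost the call without control replicates 1, 2 and 3, and 20, 24 and 27 lost it without cKO replicates 1, 2 and 3. Of the 18 others, 3, 1 and 7 gained a call without control replicates 1, 2 and 3. The 10 that kept it with each library left out were Acta2, Colec10, Igfbp2, Kcnf1, Myh11, Myl9, Mylk, Nkd1, Nptx2 and Ppp1r27. Exons of other genes on the opposite strand covered 6.9% of Mylk, 7.5% of Junb and 8.9% of Rrad, and the counting is not stated to use strand. Exons on the same strand covered 6.8% of Pnpla3 and 3.0% of Fgfr2, which counting by strand would not separate.

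Smooth muscle genes were lower as a group in the cKO uteri. Of 28 tested genes of the contractile apparatus and its regulators, 14 fell, none rose and 14 did not pass (limma adjusted p under 0.05 over all genes tested). Adjusted over the list alone, 18 were lower and 3 were higher. Some members of the list are not confined to smooth muscle. Myh11, the smooth muscle myosin heavy chain (chromosome 16, 14194535 to 14291372, GRCm38), fell from 32446 ± 9568 (SD, n = 3) to 1400 ± 145, a log2 fold change of -4.50 ± 0.23 (SE) with a limma adjusted p of 0.000107. Mylk, the kinase that phosphorylates the myosin light chain, fell from 20029 ± 1519 to 1173 ± 353, a log2 fold change of -4.13 ± 0.22. The light chain gene Myl9 had a log2 fold change of -3.45 ± 0.22 and the smooth muscle alpha-actin gene Acta2 one of -2.96 ± 0.23. The median log2 fold change over the list was -2.20, and camera gave the list an adjusted p of 2.74e-20 (adjusted p = 0.275 with an estimated correlation). Genes of autonomic and enteric neurons, a list chosen after seeing the data, took 0.00702% of reads in control replicate 2 and 0.0657% in control replicate 3, against at most 0.000288% in a cKO library and 0.000329% in control replicate 1. Genes of intestinal epithelium, also chosen after seeing the data, took 0.00941% of reads in control replicate 2 and at most 0.000644% in any other library, and skeletal muscle genes took 4.61 ± 1.51% of control and 8.33 ± 1.51% of cKO reads.

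**Figure D1:**
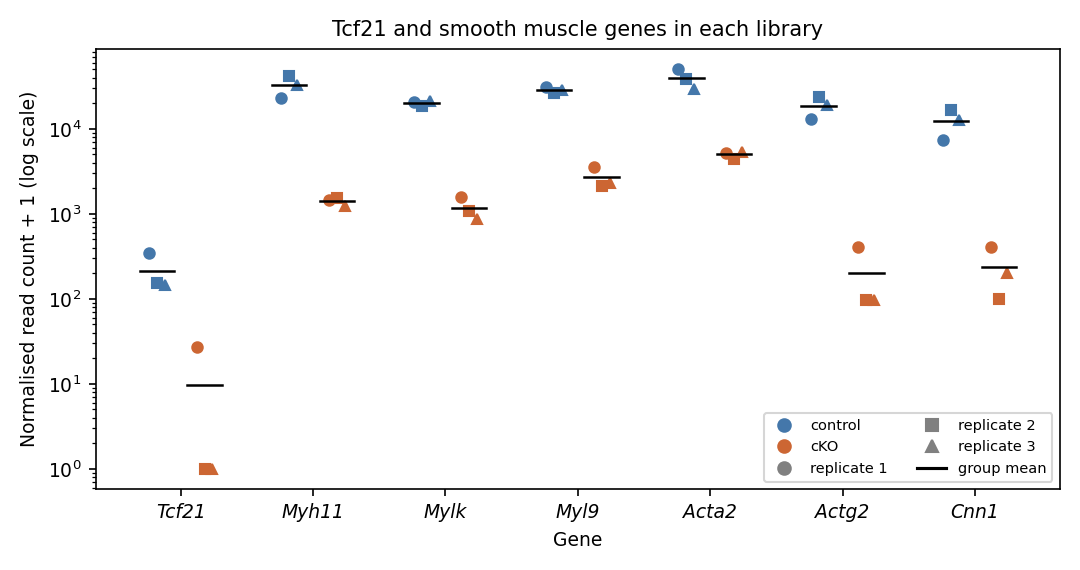
Normalised read count plus 1 (vertical axis, logarithmic) of Tcf21 and 6 smooth muscle genes (horizontal axis) in each of the 3 control and 3 cKO libraries, with black lines at the group means. For Myh11 the cKO mean of 1400 lies below the control mean of 32446, and in all 7 genes the cKO libraries lie below the controls.

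Skeletal muscle genes were abundant in all 6 libraries and higher in the cKO mean. The skeletal alpha-actin gene Acta1, named after its values were seen, was at 186632 ± 47137 (SD, n = 3) in controls and 348961 ± 80618 in cKO animals. The fast-fibre myosin light chain genes Mylpf and Myl1 had log2 fold changes of 0.99 ± 0.21 and 0.94 ± 0.23 (SE), the troponin gene Tnni2 one of 0.90 ± 0.25 and the myosin heavy chain gene Myh1 one of 0.76 ± 0.24. None of the 13 tested members passed by limma over all genes, 11 had an unadjusted p under 0.05, and DESeq2 called 7. All 13 were higher in the cKO mean, 11 passed as higher adjusted over the list alone, and camera gave an adjusted p of 8.47e-07 (adjusted p = 0.425 with an estimated correlation). A list of 18 liver genes, chosen after seeing the data, took 1.78% of the reads of control replicate 1 and at most 0.0134% in any other library. Mitochondrially encoded genes took 23.3% of the reads of control replicate 1 and 7.92 to 13.3% in the other libraries.

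**Figure D2:**
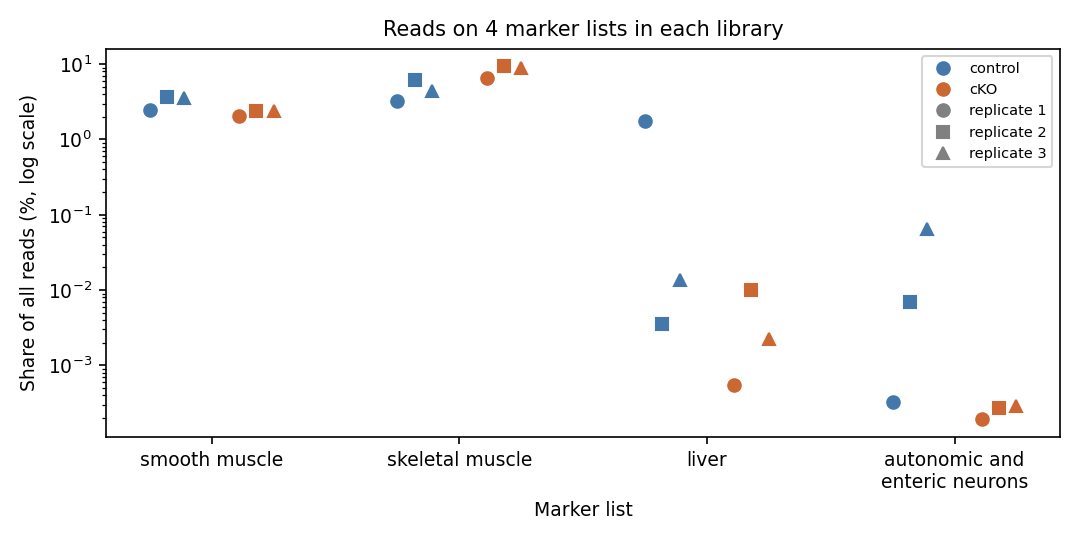
Share of all reads, in percent on a logarithmic vertical axis, that fell on marker genes of smooth muscle, skeletal muscle, liver and autonomic or enteric neurons (horizontal axis) in each of the 3 control and 3 cKO libraries. Skeletal muscle genes took 3.22 to 9.35% of reads in every library, liver genes reached 1.78% in control replicate 1 and neuron genes 0.0657% in control replicate 3. A share is a sum in which abundant genes count most. For smooth muscle it was 3.25 ± 0.674% in controls and 2.28 ± 0.202% in cKO libraries (SD, n = 3). Some genes of the smooth muscle list are not confined to smooth muscle, so this share does not measure smooth muscle alone. The median log2 fold change of that list was -2.20, with 6 of its 28 tested genes higher in the cKO mean.

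Single genes of the Wnt, BMP and TGF-beta and growth factor lists were lower in the cKO uteri, while the lists as wholes did not pass camera. In the list of Wnt targets and feedback genes, 1 of 12 tested genes fell, and 1 was lower adjusted over the list alone. It was Nkd1, a cytoplasmic antagonist of Wnt signalling, which fell from 664 ± 133 to 98.8 ± 18.7 (SD, n = 3), a log2 fold change of -2.73 ± 0.24 (SE). Among 18 Wnt ligands and secreted inhibitors 1 fell, and 2 were lower adjusted over the list alone. The R-spondin gene Rspo3 fell from 403.7 ± 179 to 55.7 ± 21.7, with antisense exons over 13.1% of its own, and the ligand gene Wnt5a, at 574 ± 124 and 282.7 ± 34.2, missed the threshold. Among 25 genes of the bone morphogenetic protein and transforming growth factor pathways 3 fell, and adjusted over the list alone 4 were lower and 1 higher. Among those that fell were the transcriptional inhibitor gene Id2 (log2 fold change -1.02 ± 0.17) and the latent growth factor binding protein gene Ltbp1 (-1.07 ± 0.20). Of 21 growth factor signalling genes 2 fell, Igfbp2 from 859.7 ± 259 to 42.3 ± 22.1 and the fibroblast growth factor receptor gene Fgfr2 from 961.7 ± 283 to 48.7 ± 40.8 (log2 fold changes of -5.38 and -3.83 without cKO replicates 1 and 2), and adjusted over the list alone 2 were lower and 1 higher. The median log2 fold change over that list was 0.27 and the mean was -0.27, and camera ranked it upwards. The camera adjusted p values of these 4 lists were 0.0816, 0.49, 0.629 and 0.557.

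Transcription factor genes of the mesenchyme were lower as a list. Of 25 tested, 2 fell and 23 did not pass, and adjusted over the list alone 5 were lower and 1 higher. The median log2 fold change was -0.42, and camera gave an adjusted p of 0.00637 (adjusted p = 0.497 with an estimated correlation). The list did not pass without control replicate 1 (camera adjusted p = 0.12) or without cKO replicate 2 (0.0655). In the same libraries, skeletal muscle genes took 4.61 ± 1.51% (SD, n = 3) of control reads and 8.33 ± 1.51% of cKO reads. A list of 8 uterine mesenchyme genes, chosen after seeing the data and sharing members with this one, took 0.0351 ± 0.0125% and 0.011 ± 0.00352%. The homeobox gene Meis2 was among those that fell, with a log2 fold change of -1.52 ± 0.24 (SE, n = 3 per group). Among regulators of decidualization, the differentiation of the uterine stroma, limma called none of 15, 6 had an unadjusted p under 0.05, DESeq2 called 4, and 2 were lower adjusted over the list alone. In the cKO mean 7 of these genes were higher and 8 lower, with a median log2 fold change of -0.014 and a camera adjusted p of 0.277. In that list Hand2 was at 302.4, 436.8 and 1107.6 in controls and 72.5, 14.6 and 48.6 in cKO animals, with a limma adjusted p of 0.0539 and opposite-strand exons over 19.6% of its own. The Hand2 log2 fold change was -3.13 without cKO replicate 2, and it passed without control replicate 1 (-4.18, limma adjusted p = 0.0316). Hand2 is also expressed in autonomic neurons, and autonomic and enteric neuron genes took 0.000329, 0.00702 and 0.0657% of reads in control replicates 1 to 3 and at most 0.000288% in a cKO library. Foxo1 in the same list had a log2 fold change of -1.18 ± 0.23 and a limma adjusted p of 0.0527, and 4 other genes share near-identical stretches with it. In the authors' deposited comparison the adjusted p was 0.000291 for Hand2 and 0.000348 for Foxo1.

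Among the genes of uterine patterning and steroid response described here, limma called Fgfr2 alone. The authors' deposited comparison lists Hoxa10, Hoxa11, Pgr, Esr1 and Akr1c14 as lower too. Its adjusted p values for them were 0.000367, 0.0147, 0.00126, 0.018 and 2.68e-05. The patterning genes Hoxa10 and Hoxa11 had log2 fold changes of -1.66 ± 0.48 and -4.10 ± 1.23 (SE, n = 3 per group), with limma adjusted p values of 0.191 and 0.221. For Hoxa11 the log2 fold change was -3.32 without control replicate 1, -5.18 without control replicate 3 and -3.07 without cKO replicate 3, with no call in any of these fits. Hoxa11 was at 896.2, 470.0 and 67.6 in control replicates 1 to 3, and antisense exons covered 35.0% of it. Of 11 Hox genes of the reproductive tract limma called none, 5 had an unadjusted p under 0.05, DESeq2 called 2, adjusted over the list alone 3 were lower and 1 higher, and the camera adjusted p was 0.277. Of 16 Müllerian duct development genes 1 fell, Fgfr2, 2 were lower adjusted over the list alone, and the camera adjusted p was 0.12 (0.00904 without control replicate 3). Among 7 steroid hormone receptor genes limma called none, 1 had an unadjusted p under 0.05, DESeq2 called 2, and none passed adjusted over the list alone. The progesterone receptor gene Pgr was at 1451 ± 653 (SD) in controls and 513 ± 210 in cKO animals and the estrogen receptor gene Esr1 at 1237 ± 755 and 484 ± 159. Without control replicate 3, Esr1 had a log2 fold change of -1.77 and a limma adjusted p of 0.0257. Camera gave the receptor list an adjusted p of 0.0422 (adjusted p = 0.425 with an estimated correlation), and the list passed with control replicate 3 left out (0.0414) but with none of the other libraries left out in turn (0.0742 to 0.277). Of 10 steroid metabolism genes limma called none, 4 had an unadjusted p under 0.05, DESeq2 called 2, and 1 was lower adjusted over the list alone, with a median of -0.67 and a camera adjusted p of 0.0283 (adjusted p = 0.513 with an estimated correlation). It did not pass without control replicate 1 (0.346) or without cKO replicate 2 (0.0944). Steroid metabolism genes took 0.099, 0.0863 and 0.0375% of reads in control replicates 1 to 3 and 0.022 to 0.0272% in the cKO libraries. In the same libraries, liver genes took 1.78% of reads in control replicate 1 and at most 0.0134% in any other, and skeletal muscle genes took 4.61 ± 1.51% (SD, n = 3) of control reads and 8.33 ± 1.51% of cKO reads. Akr1c14, a hydroxysteroid dehydrogenase gene of that list, had a log2 fold change of -1.46 ± 0.35. Of 18 estrogen response genes, 5 were higher and 13 lower in the cKO mean, limma called none, 1 had an unadjusted p under 0.05, DESeq2 called 1, and none passed adjusted over the list alone. Of 15 progesterone response genes, 6 were higher and 9 lower, limma called none, 6 had an unadjusted p under 0.05, DESeq2 called 2, and 1 was lower adjusted over the list alone. The medians of these lists were -0.60 and -0.19, and both had a camera adjusted p of 0.277. Without control replicate 3 both passed as lower (0.0124 and 0.0279), and without control replicate 1 the estrogen response list was ranked upwards (0.792). Hoxa10, Hoxa11, Pgr and Esr1 were lowest among the controls in replicate 3, the library with 0.0657% of reads on neuron genes.

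Pan-epithelial markers were lower as a list, while the lists of luminal epithelium, glandular epithelium and endometrial stroma did not pass camera, and limma called no member of any of them. All 19 tested pan-epithelial genes were lower in the cKO mean, 7 at an unadjusted p under 0.05, with 4 called by DESeq2 and none passing adjusted over the list alone. Their median log2 fold change was -1.58 and the camera adjusted p was 6.01e-05 (adjusted p = 0.558 with an estimated correlation, 0.112 without control replicate 1). The keratin gene Krt19 was at 479 ± 227 (SD, n = 3) in controls and 151 ± 56.5 in cKO animals, and the protease inhibitor gene Spint2 at 1602 ± 853 and 663 ± 108. Pan-epithelial genes took 0.0674% of reads in control replicate 1, the library with 1.78% of reads on liver genes, 0.0309% and 0.0129% in control replicates 2 and 3, and 0.00754 to 0.0137% in the cKO libraries. Intestinal epithelium genes took 0.00941% in control replicate 2 and at most 0.000644% in any other library, and skeletal muscle genes took 4.61 ± 1.51% of control and 8.33 ± 1.51% of cKO reads. Of 6 luminal epithelium genes, 2 were higher and 4 lower in the cKO mean, 1 had an unadjusted p under 0.05, and neither DESeq2 nor the adjustment over the list alone gave a call, with a median of -0.74 and a camera adjusted p of 0.459. Over the 11 luminal genes listed, the median normalised read count was 80.5, 17.1 and 4.45 in control replicates 1 to 3. In cKO replicates 1 to 3 it was 12.1, 4.88 and 8.84. The luminal comparison thus rests on few reads outside control replicate 1. Of 10 glandular epithelium genes, 6 were higher and 4 lower, 2 had an unadjusted p under 0.05, and again DESeq2 and the adjustment over the list alone gave no call. The glandular median was 0.12, while the mean was -0.48 and camera ranked the list downwards (adjusted p = 0.939), or upwards without control replicate 1 (0.875), cKO replicate 1 (0.988) or cKO replicate 3 (0.961). Glandular genes took 0.395 ± 0.0175% of reads in controls and 0.409 ± 0.0595% in cKO animals. The median normalised read count over the 15 genes behind that share was 89.0, 28.8 and 45.4 in control replicates 1 to 3. In cKO replicates 1 to 3 it was 57.6, 43.9 and 23.2. A minority of abundant genes thus carried the share, which does not show that glands were unchanged. Of 24 endometrial stroma genes, 14 were lower and 10 higher in the cKO mean, 10 had an unadjusted p under 0.05 and DESeq2 called 9. Adjusted over the list alone, 6 stroma genes were lower and 2 higher, with a median of -0.32 and a camera adjusted p of 0.12.

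Immediate-early, chemokine and cytokine, and macrophage genes were higher as lists in the cKO uteri by camera with a preset correlation, in libraries that also held a higher share of reads on skeletal muscle genes (8.33 ± 1.51% against 4.61 ± 1.51%, SD, n = 3). Of 18 immediate-early genes 2 rose, Junb (log2 fold change 0.93 ± 0.16, SE) and Socs3 (0.98 ± 0.17), and 3 were higher adjusted over the list alone. Camera gave that list an adjusted p of 7.14e-05 (adjusted p = 0.275 with an estimated correlation). Of 28 chemokine and cytokine genes 1 rose, also adjusted over the list alone. It was Ccl8, a chemoattractant of monocytes, which rose from 1036 ± 164 (SD) to 2216 ± 401, and the camera adjusted p was 9.41e-05 (adjusted p = 0.413 with an estimated correlation). Of 17 macrophage genes limma called none, 7 had an unadjusted p under 0.05, DESeq2 called 5, and 6 were higher adjusted over the list alone. Their median was 0.53 and the camera adjusted p was 7.52e-06 (adjusted p = 0.425 with an estimated correlation). The complement gene C1qc was at 2020 ± 75.5 in controls and 3329 ± 417 in cKO animals, and the endotoxin co-receptor gene Cd14 at 706 ± 237 and 1570 ± 226. With control replicates 1 and 3 both left out, the macrophage and chemokine lists did not pass. That fit holds 1 control, so its spread comes from the cKO libraries alone.

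The lists of interferon response, unfolded protein and heat shock response, T and natural killer cells, B and plasma cells and mast cells did not pass camera, and limma called none of their members. Of 24 interferon response genes, 8 were higher and 16 lower in the cKO mean, 3 had an unadjusted p under 0.05, DESeq2 called 1, and none passed adjusted over the list alone. Their median log2 fold change was -0.15 and the camera adjusted p was 0.415, and the list was ranked upwards without control replicate 2 (0.927) or cKO replicate 3 (0.722). Of 20 unfolded protein and heat shock genes, 12 were higher and 8 lower, 2 had an unadjusted p under 0.05, DESeq2 called 1, and 1 was lower adjusted over the list alone. Their median was 0.038, while the mean was -0.016 and camera ranked the list downwards (adjusted p = 0.95), or upwards without control replicate 1 (0.562), cKO replicate 1 (0.944) or cKO replicate 2 (0.962). The camera adjusted p was 0.12 for 9 T and natural killer cell genes, with 8 higher in the cKO mean and 1 at an unadjusted p under 0.05. For 6 B and plasma cell genes, with 3 higher and 0 at an unadjusted p under 0.05, and for 5 mast cell genes, with 1 higher and 1 at an unadjusted p under 0.05, it was 0.866. DESeq2 and the adjustment over the list alone called 0 members of these cell type lists. The B and plasma cell median was 0.039, while the mean was -0.28 and camera ranked the list downwards. The ranking of that list turned without control replicate 1 (0.875), control replicate 3 (0.761), cKO replicate 2 (0.878) or cKO replicate 3 (0.961), and that of the mast cell list without control replicate 2 (0.925), control replicate 3 (0.761), cKO replicate 2 (0.775) or cKO replicate 3 (0.94).

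Of the lists for blood endothelium, cell cycle, hypoxia and glycolysis, neutrophils, red blood cells and the Notch pathway, limma called no member. At an unadjusted p under 0.05 they had 2, 3, 4, 2, 1 and 3 members, and DESeq2 called 3 hypoxia and glycolysis genes and 1 neutrophil gene. Adjusted over the list alone, 2 hypoxia and glycolysis genes and 1 neutrophil gene were higher. Their medians were 0.30 to 0.82 and their camera adjusted p values 0.000874 to 0.0422, with adjusted p values of 0.425 to 0.558 with an estimated correlation. The hypoxia and glycolysis list did not pass without control replicate 1 (0.096). The neutrophil list did not pass without control replicate 3 (0.152), cKO replicate 1 (0.0742) or cKO replicate 3 (0.0872). The red blood cell list did not pass without control replicates 2 (0.063) or 3 (0.12) or cKO replicates 1 (0.0554) or 2 (0.136), and the Notch list without control replicates 1 (0.127) or 2 (0.213) or cKO replicates 1 (0.0616) or 2 (0.0944). Hypoxia and glycolysis genes took 0.828, 1.6 and 1.26% of reads in control replicates 1 to 3 and 1.84, 2.45 and 2.23% in cKO replicates 1 to 3, and skeletal muscle genes took 3.22, 6.21 and 4.41% and 6.6, 9.35 and 9.03%. Vegfa, which encodes an angiogenic growth factor, had a log2 fold change of 0.72 ± 0.17 (SE, n = 3 per group). Gapdh had one of 3.71 ± 0.77, with values of 4553, 686 and 4870 in controls and 28683, 35884 and 33483 in cKO animals. Without control replicate 2, Gapdh had a log2 fold change of 2.79 and a limma adjusted p of 0.00091. With all libraries its adjusted p was 0.114 by limma and 0.00126 in the authors' deposited table, and 152 other genes share near-identical stretches with its transcripts, so its reads are uncertain. Among 10 tested Schwann cell and neuron genes, 2 rose, among them the myelin gene Mbp, from 635.5 ± 23.3 (SD) to 1444 ± 384, and Snap25 fell. Adjusted over that list alone, 2 were higher and 1 lower. Its median log2 fold change was -0.16 and its mean -0.94, while camera ranked it upwards, with an adjusted p of 0.927. It passed without control replicate 3 (0.0487) and was ranked downwards without control replicate 1 (0.188), control replicate 2 (0.925) or cKO replicate 3 (0.968).

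Camera called 15 of 47 testable lists, 10 higher and 5 lower. With an estimated correlation it called 0, 3 lists had an unadjusted p under 0.05, and the smallest adjusted p was 0.275. At the preset correlation, the other splits of the 6 libraries into 3 and 3 gave 5 to 15 called lists. The number of lists called at that setting therefore does not by itself set the real groups apart. Those splits mix the groups unevenly and keep part of the real difference, so they do not show how often chance alone gives such calls. Fry called 2 lists, smooth muscle and Wnt targets and feedback. In every list described above without a member called by limma, edgeR and limma-voom also called 0 members.

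A segment around a targeted locus can come from another mouse strain, so genes near Tcf21 were compared with the rest. The controls have floxed copies of Tcf21, so both groups may carry the same segment. The comparison therefore cannot show whether such a segment is present. Within 20 Mb on either side of Tcf21, itself left out, 2 of 179 tested genes were called, against 188 of 16135 elsewhere, an odds ratio of 0.958 (two-sided Fisher's exact test, p = 1).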

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

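The alternatives with TMM or edgeR, with pseudocounts of 0.5 and 5 and with both of control replicates 1 and 3 left out were chosen after seeing the data. In that last fit the lone control is assumed to vary like the others, and it gave 271 higher and 504 lower genes. DESeq2 called 285 higher and 584 lower genes, including all 45 and 145 of limma, while limma-voom called 19 and 82. Without a filter on low reads, 82 genes were higher and 200 lower, among them all 45 higher and 138 of the 145 lower genes of the main test. At an adjusted p of 0.01 there were 3 higher and 54 lower genes, and against a 1.5-fold minimum 1 and 45. With 1 library left out in turn, the higher genes ranged from 1 to 117 and the lower from 42 to 347. The cause of these shifts was not tested. Tcf21 was negative under all 19 alternatives (-7.62 to -4.45). It passed with a pseudocount of 5 (-4.45, adjusted p = 0.0301) and without cKO replicate 1, and ranged from -7.62 to -5.24 over the libraries left out (adjusted p from 0.00583 to 0.359).

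Camera called 0 lists with an estimated correlation and fry called 2, and the smooth muscle list had an adjusted p of 0.275 with an estimated correlation. It passed under all other alternatives run. DESeq2 and edgeR also called as lower the lists of endometrial stroma (adjusted p = 0.0382 and 0.0288), Wnt targets and feedback (0.0251 and 0.0191) and Müllerian duct development (0.0404 and 0.0345). The Notch list lost its call with both (0.0621 and 0.0539), the red blood cell list with DESeq2 (0.0784), with upper-quartile scaling (0.0662) and without a filter (0.0715), the neutrophil and steroid receptor lists without a filter (0.0845 and 0.114), and steroid metabolism with limma-voom (0.0772). With control replicates 1 and 3 left out, the macrophage, chemokine, neutrophil, red blood cell, steroid receptor, steroid metabolism and hypoxia lists did not pass (0.121, 0.212, 0.255, 0.222, 0.0663, 0.279 and 0.662). Some lists without a call turned in direction, and the cause was not tested. With DESeq2 these were growth factor signalling (adjusted p = 0.926) and Schwann cells and neurons (0.98), with edgeR growth factor signalling (0.823), and with limma-voom and fry glandular epithelium (0.792 and 0.897). With upper-quartile scaling they were Schwann cells and neurons and the unfolded protein and heat shock response (0.899 for both). Without a filter they were B and plasma cells (0.964) and the unfolded protein list (0.948), and with a filter of 1 CPM B and plasma cells (0.873). With control replicates 1 and 3 left out they were the BMP and TGF-beta, B and plasma cell and unfolded protein lists (0.662 for each), glandular epithelium (0.915) and decidualization regulators (0.947), and the interferon response passed as lower (0.033). With 1 library left out in turn, the adjusted p ranged from 0.749 to 0.988 for glandular epithelium, 0.0124 to 0.792 for estrogen response, 0.0487 to 0.968 for Schwann cells and neurons, 0.597 to 0.977 for B and plasma cells, 0.562 to 0.94 for mast cells, 0.0731 to 0.927 for interferon response and 0.551 to 0.966 for the unfolded protein list.

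Of 38 called genes named in the text, 8 kept the call under all alternatives (Acta2, Igfbp2, Myh11, Myl9, Mylk, Nkd1, Nptx2 and Ppp1r27) and 30 lost it under at least 1, with no change of direction in any of 56. All 18 other named genes of the rule, without a call, passed under at least 1 alternative, Tcf21 and Acta1 not counted. Genes near Tcf21 passed in none (p from 0.172 to 1).

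With the replicate number as a replicate block, there were 34 higher and 149 lower genes, 23 and 114 of them also called without the block, and Tcf21 passed (-6.03, adjusted p = 0.0126). The lists of endometrial stroma, Hox genes, Müllerian duct development and estrogen response passed (0.0116, 0.0254, 0.0405 and 0.045), and the unfolded protein list turned in direction (0.957). The deviations of same-numbered libraries from their group means correlated at 0.00843, -0.176 and 0.0438, which gives no sign that the numbers pair the animals. With 3 libraries per group, and transcripts of other tissues in some of them, these values cannot exclude pairing. Depth limits genes with few reads: 3 reads correspond to a value of up to 3.66 in controls and 3.31 in cKO libraries.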

Other observations

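All tests in this part were chosen after the results they bear on had been seen.

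Smooth muscle genes could be lower because the cKO samples held less uterine tissue of any kind, because the control samples held smooth muscle of another organ, or because of the genotype, and none of these is excluded. A list of 8 uterine mesenchyme genes, all 8 also in lists fixed before, had a median log2 fold change of -1.56 with an interquartile range of 2.06. It took 0.0351 ± 0.0125% of reads in controls and 0.011 ± 0.00352% in cKO samples (SD, n = 3). The 24 endometrial stroma genes fixed before had a median of -0.32, with 10 of them higher. They took 0.522 ± 0.0652% of reads in controls and 0.495 ± 0.0379% in cKO samples. Members that go both ways leave a smaller share of uterine tissue open. In control replicate 1, where neuron genes took 0.000329% of reads, smooth muscle genes lay a median of 1.81 log2 units above the cKO mean, but 1 library cannot exclude another organ as a source. Tissue share and genotype cannot be told apart, because they go together in these 6 animals, although the mesenchyme medians of 857, 453 and 264 in control replicates 1 to 3 did not rank those libraries as the smooth muscle medians of 5485, 7237 and 7360 did. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Of them 1 split, the real one, gave 190 changed genes against 0 at most in the others. For lists changed by camera 2 splits gave at least the real 15. The splits other than the real one gave 5 to 15 lists. Each of them mixes control and cKO libraries unevenly and so keeps part of the real difference. Their median smooth muscle log2 fold changes were between -0.678 and -0.487 or between 0.8 and 1.01. Neither the gene counts nor the list counts of these splits therefore show how often chance alone gives such calls.

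Skeletal muscle transcripts were abundant in libraries labelled uterus. All 13 tested genes of the list were in the top 10% of tested genes in all 6 libraries, which is consistent with skeletal muscle tissue in the samples, and none of them is in another fixed list. Reads of near-identical copies are an unlikely source, since 12 of the 13 have no copy of at least 95% identity over at least 100 bases and those 12 were all in the top 10%. Whether the higher share in the cKO samples came from dissection or from the genotype was not tested.

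Gapdh was 13.1 times higher in the cKO samples on the fitted scale, without passing the test, or 6.91 times and past it without control replicate 2, while 10 other glycolysis genes were on average 1.62 times higher and 30 tested pseudogene copies, summed, 1.77 times higher. Had reads of Gapdh only been counted at those copies, the sum of Gapdh and copies would differ like the other glycolysis genes, but it differed by 2.09 ± 0.609 (SE) log2 units more, and by 1.496 ± 0.201 more without control replicate 2. The copies alone differed by 0.12 ± 0.24 more than the glycolysis genes, and by 0.33 ± 0.13 more without control replicate 1. Gapdh reads left out of the control counts may play a part, and this cannot be told apart from a change in the gene, because reads that were not counted are not analysed here.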
